A study of Mus musculus with 24 samples.

How the data were processed

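The values analysed are the raw gene counts that the authors deposited, 1 table of 54232 mouse genes for each of 24 libraries. The submitters' notes describe total RNA from snap-frozen wound tissue isolated with a miRNeasy kit, removal of ribosomal RNA with Ribo-Zero and libraries made with the NEBNext Ultra RNA kit, which does not mark the strand. The same notes name bcl2fastq 2.17, FastQC, cutadapt, STAR alignment to the mouse genome GRCm38 and counting with featureCounts. The authors' annotation release is not given in the sources used here. Because reads carry no strand, a gene's count can include reads from a gene that overlaps it on the opposite strand.

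Gene symbols and coordinates come from GENCODE M21 on GRCm38, which holds 54079 of the gene identifiers with a symbol. Genes with too few counts were removed with the edgeR function filterByExpr with its default settings, which left 18978 genes, and library sizes were scaled with the trimmed mean of M-values (TMM). A single edgeR quasi-likelihood model with robust dispersion was fitted to all libraries with 1 term per group. From it came the 10 comparisons between pairs of groups, the mean of the 4 media against Ctrl, and a test for any difference among the 5 groups. The Benjamini-Hochberg adjusted p of edgeR was compared with 0.05, and 95% intervals of log2 fold changes come from the same model. CPM are counts scaled to a common library size after TMM scaling and their ± is an SD over libraries. The counts by other tools come from DESeq2 with its default filtering and from limma with voom and sample quality weights. A tool's adjusted p is named beside it where it is not that of edgeR. A gene counted as measured at 1 CPM or more when its average log2 CPM was at least 0, which held for 18573 genes.

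Gene lists for cell types, pathways and RNA quality, 31 lists with 635 entries, were fixed before the data were examined. Those of skeletal muscle, hair follicle, sebaceous gland, adipocytes, melanocytes, Schwann cells and erythrocytes were included as checks of what the tissue taken held. A shift in them can reflect the tissue taken as well as the medium. Of the entries 628 were matched by symbol, 5 by a synonym and 2 not at all, and 575 were tested. Lists with at least 5 tested members were compared with camera of limma on log2 CPM (prior count 2) with a preset correlation between genes of 0.01 and, as an alternative, a correlation estimated from the libraries. The camera p-values are adjusted over the 31 lists. A list score is the mean log2 CPM of the tested members, and scores were compared with an exact permutation test over all divisions of the libraries, two-sided and adjusted over the 31 lists. An exact permutation p is printed unadjusted unless it is called adjusted. The smallest exact permutation p is 0.00476 for 4 libraries against the 6 controls and 0.00216 for 5 against 6, and 0.0286 for 4 against 4. A mean shift of a list is the difference of its group mean scores, and for the mean of the media the 4 media have equal weight.

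Genes named in the text follow a rule fixed at the same time. They are the genes past the threshold, of which edgeR gave 0, the 2 members with the smallest p in each called list (in the 5 lists with the smallest p for comparisons between media and for the mean), and a panel of 24 genes in each comparison with Ctrl. Genes outside that rule are said to have been chosen after their values were seen. Reads of close paralogs cannot always be told apart, which concerns the Stfa3 and Serpinb3a families, globins, hair keratins, Sprr2d, Cd209a, Ccl3 and Ccl4, and ribosomal protein genes with processed pseudogenes. Coordinates are given as chromosome, start and end on GRCm38.

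In a self-test on simulated counts with 200 genes changed among 18978, edgeR recovered between 28.4% and 47.8% of genes changed 1.5-fold, between 50.7% and 71.6% of genes changed 2-fold in the comparisons between pairs of groups, and between 86.4% and 95.5% of those changed 4-fold. Each gene was drawn independently, without the variation that genes of a real library share, so these rates need not hold for the real libraries. For lists of independent genes camera called 0. The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.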

Results

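Gene expression was measured by RNA sequencing in back skin wounds of male db/db mice, which carry a mutated leptin receptor on the C57BLKS/J background and become obese and diabetic. Wounds 6 mm across were made with a biopsy punch at 16 weeks of age and covered at once with an alginate bandage. The bandage was a control bandage (Ctrl, n = 6 mice) or carried medium conditioned by primary macrophages in the M0 (CM0, n = 4), M1 (CM1, n = 4), M2a (CMA, n = 5) or M2c (CMC, n = 5) state. M0 is the usual name for macrophages without a polarising stimulus, M1 for an inflammatory state, and M2a and M2c for states tied to repair and to resolution; the stimuli used to obtain them are not given in the sources used here. Bandages were renewed on day 3 and the tissue was taken on day 10, at 17.5 weeks of age, which gave 24 libraries. Total counts were 9510741, 8329003, 9142657, 7267879, 7961049 and 11985292 in Ctrl 1 to Ctrl 6, 10826300, 9679936, 9777258 and 10730679 in CM0, and 8746185, 11958892, 9768298 and 9442587 in CM1. They were 8365530, 8323331, 9042344, 8665555 and 10259818 in CMA and 9186670, 9580704, 8561677, 8703886 and 11632421 in CMC. Protein-coding genes held 90.3% of all counts. The matrix of the healing dermis was prominent in all libraries together, with 2.84% of all counts from Col3a1 and 2.74% from Col1a1, the main fibrillar collagens of granulation tissue, beside 3.43% from the non-coding gene Gm26917.

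Single genes did not separate the 5 kinds of wound. Among 18978 genes tested for any difference between the groups, edgeR called 0 at an adjusted p under 0.05 and 882 had an unadjusted p under 0.05, where chance alone gives 949. DESeq2 called 1 gene in the same test, Fibin (ENSMUSG00000074971, chromosome 2, 110360917 to 110363183), and limma with sample quality weights called 0. Fibin, a secreted factor of limb development, stood at 18.5 ± 2.99 CPM (counts scaled by library size) in Ctrl, 37.3 ± 9.78 in CM0, 43 ± 17.1 in CM1, 19.8 ± 7.29 in CMA and 28.7 ± 5.14 in CMC (mean ± SD), with an adjusted p = 0.0087 in DESeq2. It was chosen for mention after its values were seen, as were the other genes named below only because DESeq2 or a fit without 1 library called them. Group membership accounted for 17.4% of the variance between libraries, and randomly permuted group labels for 17.4% on average (permutation p = 0.473).

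Large differences between single libraries lay in genes of skin appendages, inflammatory cells, activated epidermis and muscle. For each of 31 fixed gene lists, a library's score was the mean log2 CPM of the list's tested members. The hair follicle list, which holds the keratins of the hair shaft and inner root sheath, spanned 289-fold between the highest and lowest library. Its scores were 7.56 in Ctrl 3, 4.97 in CMA 3 and 4.74 in Ctrl 4. The melanocyte list of pigment genes spanned 26.9-fold and was also highest in Ctrl 3, at 5.28. The chemokine list, made of signals that draw in neutrophils and monocytes, spanned 10.6-fold, from 1.21 in Ctrl 4 to 4.61 in CM1 3. The neutrophil list spanned 8.34-fold between the same libraries, from 1.81 to 4.87. Wound keratinocyte genes, those of the activated epidermis at a wound edge, spanned 6.39-fold, from Ctrl 2 to CMC 1, and skeletal muscle genes 5.28-fold, with the highest score in Ctrl 4 and the lowest in CMA 3. The hair follicle, melanocyte and muscle lists had been fixed as checks of what the tissue taken held.

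**Figure D1:**
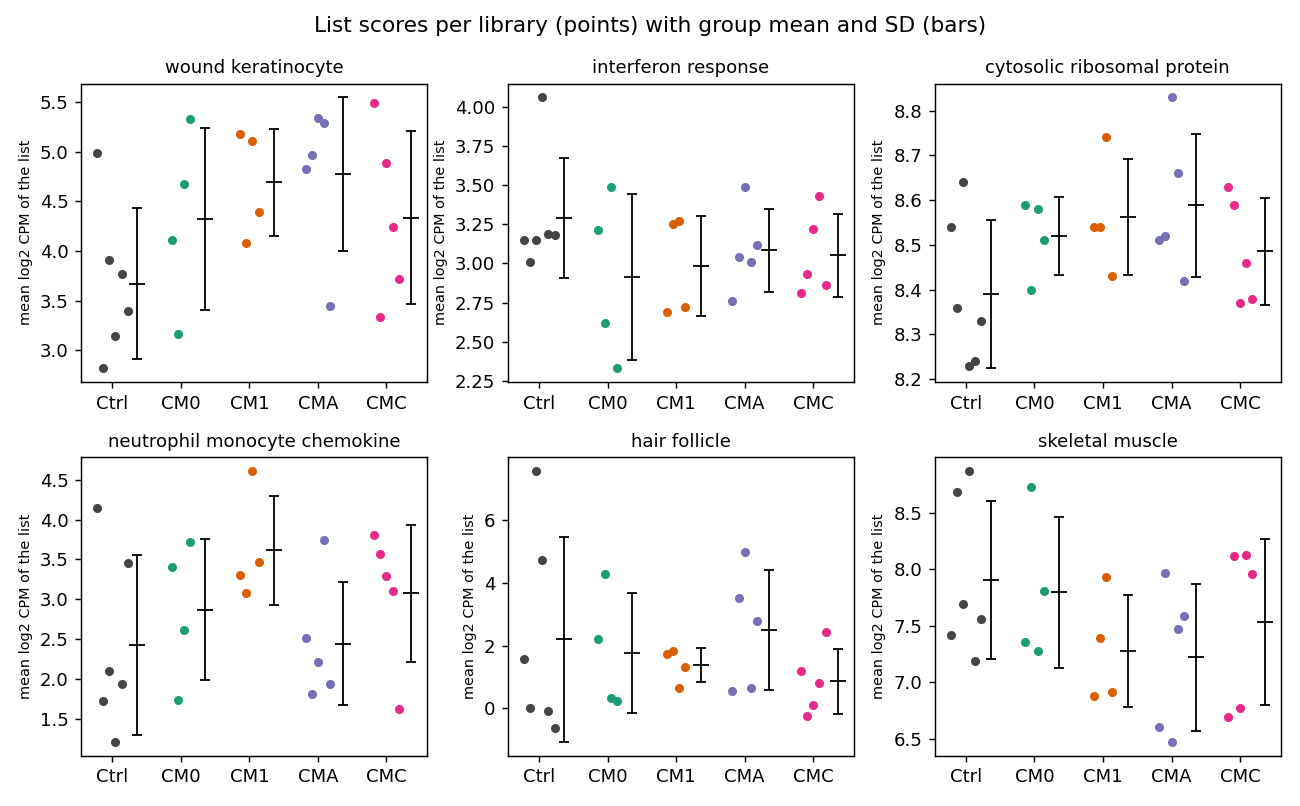
Each point is the score of a gene list in 1 library (mean log2 CPM of the list's tested members), by bandage group, with the group mean and SD as a bar. In each of the 6 lists drawn the libraries of each medium overlap the range of Ctrl, and Ctrl 3 stands apart at 7.56 in the hair follicle list.

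Gene lists were compared between groups with camera, which asks whether the members of a list are shifted together against all other genes. With its preset correlation between genes it called 8 to 18 of the 31 lists in each comparison of a pair of groups, and with the correlation estimated from these libraries it called 0 in every comparison. The test fry called 0 as well. Other divisions of the same libraries into groups of the same sizes gave a median of 9 to 13 called lists. A called list is therefore described below by the direction and size of its members, with both adjusted p-values. Adjusted p-values for single genes come from edgeR.

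**Figure D2:**
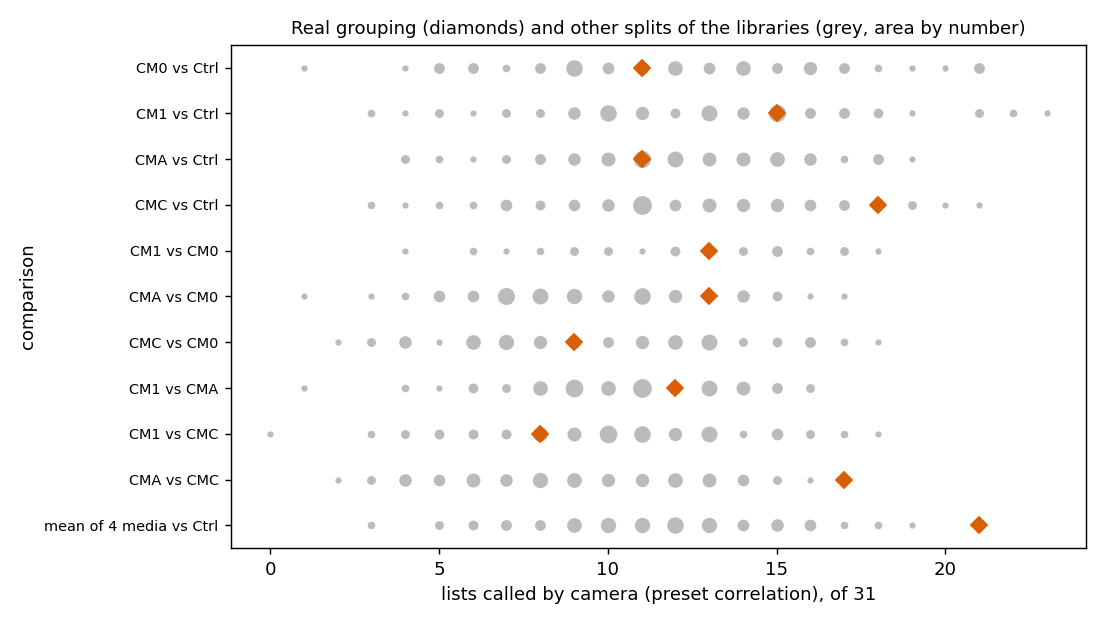
Number of the 31 gene lists called by camera in each comparison, for the real groups and for other divisions of the same libraries into groups of the same sizes. The real count lies above all other divisions drawn for CMA against CMC (17, highest other 16) and for the mean of the media against Ctrl (21, highest other 19), and within their range in the other comparisons.

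To see what medium from M0 macrophages does, CM0 wounds were compared with control wounds. Genes of the differentiating epidermis were higher under CM0. Krt10 (ENSMUSG00000019761, chromosome 11, 99385254 to 99389364), the keratin of suprabasal keratinocytes, stood at 2310 ± 594 CPM (SD, n = 4) against 1360 ± 337 in Ctrl (n = 6), a log2 fold change of 0.77 (SE 0.27, 95% interval 0.21 to 1.32), and lay above the control median in 4 of 4 libraries. Of the cornified keratinocyte list 21 of 23 members were higher and the median log2 fold change was 0.40 (camera adjusted p = 5.42e-06, and adjusted p = 0.91 with an estimated correlation). Krt2 (ENSMUSG00000064201, chromosome 15, 101810689 to 101818169), a keratin of the upper epidermis, went the other way, with 32.1 ± 16.3 against 73.2 ± 37.6 CPM. The wound keratinocyte list had 20 of 21 members higher with a median of 0.65 (adjusted p = 1.5e-04, and adjusted p = 0.91 with an estimated correlation). In it Il1f6 (ENSMUSG00000026984, chromosome 2, 24215418 to 24225702), the epithelial cytokine IL-36 alpha, had a log2 fold change of 1.17 (SE 0.47). Without CM0 4 the wound keratinocyte call ended (adjusted p = 0.216), while the cornified call held without any 1 library, with a mean shift of 0.40, or 0.22 without Ctrl 6.

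Dermal matrix genes were higher under CM0 and interferon-induced genes lower. The fibrillar collagen and matrix list had 24 of 27 members higher, with a median of 0.25 (adjusted p = 3.83e-06, and adjusted p = 0.91 with an estimated correlation). Serpinh1 (ENSMUSG00000070436, chromosome 7, 99345376 to 99353239), the chaperone of collagen folding, stood at 1020 ± 35.5 against 802 ± 134 CPM (log2 fold change 0.34, SE 0.14). Of the interferon response list 28 of 29 members were lower, with a median of -0.36 (adjusted p = 6.44e-09, and adjusted p = 0.91 with an estimated correlation). Ctrl 4 had the highest interferon score of all libraries. All 28 cytosolic ribosomal protein genes were higher, by a median of 0.13 (adjusted p = 4.19e-08, and adjusted p = 0.91 with an estimated correlation). The matrix, interferon and ribosomal protein calls held without any 1 library, but the mean shift of the interferon list, -0.38, was -0.22 without Ctrl 4, -0.18 without CM0 4 and -0.57 without CM0 3.

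Blood vessel genes were higher under CM0 and macrophage genes lower, by small amounts. Tek (ENSMUSG00000006386, chromosome 4, 94739289 to 94874976), the angiopoietin receptor of endothelial cells, stood at 47.1 ± 10.4 against 31.5 ± 5.79 CPM (log2 fold change 0.58, SE 0.16, adjusted p = 0.95) and passed when adjusted over the list alone, 1 of 21 endothelial genes, against 0 over all genes. The endothelial list had a median of 0.10 (adjusted p = 0.0168), the macrophage list -0.18 with 19 of 20 members lower (adjusted p = 0.0303), the growth factor list 0.16 (adjusted p = 0.0352), the matrix protease list 0.16 (adjusted p = 0.0274), the chemokine list 0.09 (adjusted p = 0.0405) and the cell cycle list -0.14 with 26 of 27 lower (adjusted p = 0.00899), each with an adjusted p = 0.91 with an estimated correlation. These calls rested on few libraries. The endothelial call ended without Ctrl 2, Ctrl 3, CM0 1 or CM0 4 (adjusted p up to 0.708), the macrophage call without Ctrl 5, Ctrl 6, CM0 2 or CM0 4 (up to 0.389) and the growth factor call without Ctrl 2, Ctrl 3, Ctrl 4, CM0 1 or CM0 4 (up to 0.249). The matrix protease call ended without Ctrl 2, Ctrl 3, Ctrl 4, CM0 1, CM0 3 or CM0 4 (up to 0.31), the chemokine call without any of these or Ctrl 5 (up to 0.616) and the cell cycle call without Ctrl 3, Ctrl 6 or CM0 4 (up to 0.764). The lymphatic endothelial list was not called by camera, but its score separated the groups fully, at 3.99 ± 0.14 in CM0 and 3.77 ± 0.12 in Ctrl. The lowest CM0 score was 3.86 and the highest Ctrl score 3.84. Its exact permutation p = 0.00476 is the smallest that the 210 divisions allow, and it was 0.148 when adjusted over the 31 lists. When each member was first scaled to the same mean and SD over the libraries, the lowest adjusted exact permutation p of any list was 0.93.

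edgeR called 0 genes between CM0 and Ctrl, with 933 at an unadjusted p under 0.05 against 949 by chance. limma with sample quality weights called 0 and DESeq2 1, Vgll3 (ENSMUSG00000091243, chromosome 16, 65815257 to 65866368), a cofactor of TEAD transcription factors (log2 fold change 0.40, SE 0.08, adjusted p = 0.027 in DESeq2 and 0.53 in edgeR). edgeR also called Vgll3 when CM0 2 was left out (log2 fold change 0.47, adjusted p = 0.031). For 85.5% of the 18573 genes with a mean of at least 1 CPM the 95% interval of the fold change lay within 2-fold in either direction, so larger changes of those genes are excluded at that level. Camera called 11 lists, 8 higher and 3 lower, and 6 without Ctrl 3, 7 without CM0 1 and 4 without CM0 4.

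CM1 wounds were compared with control wounds to see the effect of medium from M1 macrophages. Genes of neutrophils and of the chemokines that attract them were higher, with much of the excess in 1 library. S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), a calcium-binding protein abundant in neutrophils, stood at 200 ± 112 CPM (SD, n = 4) against 48.6 ± 45.4 in Ctrl (n = 6), a log2 fold change of 2.03 (SE 0.82, adjusted p = 0.69). Of the neutrophil list 17 of 19 members were higher, with a median of 1.04 and scores of 3.82 ± 0.82 against 2.75 ± 0.93 (camera adjusted p = 1.28e-06, and adjusted p = 0.46 with an estimated correlation). Of the chemokine list 13 of 14 were higher, with a median of 0.72 (adjusted p = 4.16e-06, and adjusted p = 0.46 with an estimated correlation). 2 of its members, Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683) and Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) passed when adjusted over the list alone and 0 over all genes. Ccl4 stood at 55.72 CPM in CM1 3 and its log2 fold change was 2.99, or 0.65 without that library; that of Ccl3 was 2.06, or 0.30 without it. Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), the inflammatory cytokine, had a log2 fold change of 1.19 (SE 0.44), and -0.002 without CM1 3. Both lists stayed called without any 1 library, and the mean shift of the chemokine list, 1.19, was 0.73 without CM1 3.

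Epidermal, vascular and matrix genes were also higher under CM1. The wound keratinocyte list had 19 of 21 members higher and a median of 0.90, with scores of 4.69 ± 0.54 against 3.67 ± 0.76 (adjusted p = 8.78e-08, and adjusted p = 0.46 with an estimated correlation). Sprr2d (ENSMUSG00000042212, chromosome 3, 92339140 to 92340873), a cornified envelope precursor with close paralogs, stood at 31.1 ± 16.3 against 10.2 ± 9.95 CPM. All 21 endothelial genes were higher, by a median of 0.28 (adjusted p = 8.78e-08, and adjusted p = 0.46 with an estimated correlation). Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354), a transcription factor of arterial endothelium, stood at 8.42 ± 0.957 against 6.14 ± 1.53 CPM (log2 fold change 0.45, SE 0.17); the mean shift of the endothelial list, 0.29, was 0.18 without Ctrl 3. All 28 ribosomal protein genes were higher, by a median of 0.18 (adjusted p = 2.1e-11), and the matrix protease list by 0.18 (adjusted p = 6.99e-04), both with an adjusted p = 0.46 with an estimated correlation. The fibrillar collagen and matrix list had a median of 0.27 (adjusted p = 1.39e-05, and 0.144 without CM1 4), the alternative activation list of M2-type macrophage genes 0.28 (adjusted p = 0.00134, and 0.165 without CM1 2) and the monocyte and dendritic cell list 0.23 (adjusted p = 4.89e-04, and up to 0.0558 without Ctrl 3 or CM1 2), each with an adjusted p = 0.46 with an estimated correlation. In the last of these Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), the receptor that brings inflammatory monocytes into tissue, stood at 53.4 ± 13.1 against 33.2 ± 14.9 CPM.

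Lower under CM1 were genes of the mitochondrial genome, cell division, muscle, interferon response, hair and pigment. The score of the mitochondrially encoded genes was 6.16 ± 0.08 against 6.43 ± 0.18 (exact permutation p = 0.019, and 0.492 adjusted over the 31 lists). 10 of its 11 genes were lower and 4 passed when adjusted over the list alone, 0 over all genes (median -0.33, camera adjusted p = 4.04e-06, and adjusted p = 0.46 with an estimated correlation). mt-Cytb (ENSMUSG00000064370, chromosome M, 14145 to 15288), the cytochrome b subunit of respiratory complex III, stood at 570 ± 19.6 against 714 ± 104 CPM. All 27 cell cycle genes were lower, by a median of -0.29 (adjusted p = 8.78e-08, and adjusted p = 0.46 with an estimated correlation). Nusap1 (ENSMUSG00000027306, chromosome 2, 119618298 to 119651244), a spindle protein, stood at 10.9 ± 1.4 against 14.4 ± 3.76 CPM; without Ctrl 3, Ctrl 4 and CM1 3 together the mean shift of the cell cycle list was 0.018. All 23 skeletal muscle genes were lower (median -0.73, adjusted p = 1.08e-06, and adjusted p = 0.47 with an estimated correlation), as were 28 of 29 interferon response genes (median -0.34, adjusted p = 1.24e-05, and adjusted p = 0.50 with an estimated correlation). The muscle and interferon scores were highest in Ctrl 4. These 4 calls held without any 1 library, but the mean shift of the interferon list, -0.31, was -0.16 without Ctrl 4, and that of the cell cycle list, -0.26, was -0.15 without Ctrl 3 and -0.14 without CM1 3.

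The hair and pigment calls of CM1 rested on single libraries, above all a pair of controls. Krt83 (ENSMUSG00000067613, chromosome 15, 101485130 to 101491512), a keratin of the hair shaft, stood at 231.26 CPM in Ctrl 3 and 6.89 in Ctrl 4, and at 0.46 ± 0.0695 CPM in CM1, where it lay above the control median in 4 of 4 libraries. Its log2 fold change was -6.41 (SE 1.95), and -1.60 without Ctrl 3. It was -0.69 in limma with sample quality weights, and 1.30 without Ctrl 3, Ctrl 4 and CM1 3 together. All 16 hair follicle genes were lower (median -4.26) and 15 passed when adjusted over the list alone, 0 over all genes (adjusted p = 0.0147, and adjusted p = 0.73 with an estimated correlation). The hair follicle scores of CM1, 0.66 to 1.84, nevertheless lay above those of Ctrl 2, Ctrl 5 and Ctrl 6, at 0, -0.08 and -0.61. The mean shift of the list was -0.81, and 0.26 without Ctrl 3, and the call ended without Ctrl 3 or Ctrl 4 (adjusted p up to 0.939). All 9 melanocyte genes were lower (median -2.43) and 7 passed over the list alone, 0 over all genes (adjusted p = 0.0121, and adjusted p = 0.53 with an estimated correlation). That call ended without Ctrl 3, Ctrl 4 or CM1 3 (adjusted p up to 0.525).

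edgeR called 0 genes between CM1 and Ctrl, with 1337 at an unadjusted p under 0.05. limma with sample quality weights called 0 and DESeq2 1, Fibin (log2 fold change 1.21, SE 0.25, adjusted p = 0.049 in DESeq2 and 0.69 in edgeR). The interval lay within 2-fold for 84.2% of the 18573 genes. Camera called 15 lists, 9 higher and 6 lower, and 10 without Ctrl 3, Ctrl 4 and CM1 3 together.

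CMA wounds were compared with control wounds to see the effect of medium from M2a macrophages. Keratinocyte genes of the basal, the cornified and the activated epidermis were higher. Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548), the keratin of the basal layer, stood at 3810 ± 1060 CPM (SD, n = 5) against 2110 ± 834 in Ctrl (n = 6), a log2 fold change of 0.85 (SE 0.31, 95% interval 0.21 to 1.5, adjusted p = 0.73), and Krt10 at 2170 ± 863 against 1360 ± 337 CPM, a log2 fold change of 0.68 (SE 0.25); both lay above the control median in 5 of 5 libraries, and without CMA 3 the log2 fold change of Krt10 was 0.41. All 23 cornified keratinocyte genes were higher, by a median of 0.59, with scores of 7.85 ± 0.29 against 7.26 ± 0.53 (exact permutation p = 0.0455; camera adjusted p = 5.49e-11, and adjusted p = 0.60 with an estimated correlation). Ivl (ENSMUSG00000049128, chromosome 3, 92570902 to 92573735), involucrin of the cornified envelope, stood at 64.2 ± 22.1 against 38.4 ± 14.1 CPM. Of the wound keratinocyte list 19 of 21 members were higher, by a median of 0.99, with scores of 4.78 ± 0.77 against 3.67 ± 0.76 (exact permutation p = 0.0498; camera adjusted p = 9.14e-11, and adjusted p = 0.60 with an estimated correlation). 4 of them passed when adjusted over the list alone, 0 over all genes, among them Il1f6, with a log2 fold change of 1.63 (SE 0.45), and Serpinb3a (ENSMUSG00000044594, chromosome 1, 107045587 to 107052303), an epidermal protease inhibitor with close paralogs, at 13.9 ± 19.4 against 2.09 ± 1.63 CPM. Without CMA 3 the log2 fold change of Il1f6 was 1.04 and that of Serpinb3a 1.30 in place of 2.70. The smaller shift of the basal keratinocyte list (median 0.26, adjusted p = 0.00188, and adjusted p = 0.60 with an estimated correlation) was no longer called without Ctrl 6 (adjusted p = 0.0633).

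Early response and ribosomal protein genes were higher under CMA as well. Of the immediate early list 16 of 19 members were higher, by a median of 0.24 (adjusted p = 2.19e-04, and adjusted p = 0.60 with an estimated correlation), and 3 passed when adjusted over the list alone, 0 over all genes. Its mean shift, 0.24, was 0.14 without CMA 3. Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466), a transcription factor of the differentiating epidermis, stood at 192 ± 47.2 against 128 ± 27.6 CPM (log2 fold change 0.59, SE 0.16), and Dnajb1 (ENSMUSG00000005483, chromosome 8, 83608193 to 83612653), a heat shock co-chaperone, at 61.0 ± 5.71 against 47.8 ± 7.27. All 28 ribosomal protein genes were higher, by a median of 0.19 (adjusted p = 1.33e-16, and adjusted p = 0.60 with an estimated correlation). Rps2 (ENSMUSG00000044533, chromosome 17, 24718116 to 24721929), a protein of the small subunit, stood at 666 ± 86.5 against 548 ± 50.4 CPM. The monocyte and dendritic cell list had a median of 0.13 (adjusted p = 0.0393) and the hypoxia and glycolysis list 0.08 (adjusted p = 0.0418), both with an adjusted p = 0.90 with an estimated correlation. The former was called in 6 of 11 fits that left out 1 library, and lost without Ctrl 3, Ctrl 5, CMA 1, CMA 2 or CMA 5 (adjusted p up to 0.695). The latter was called in 3 of 11, and lost without Ctrl 2, Ctrl 3, Ctrl 4, Ctrl 5, Ctrl 6, CMA 1, CMA 2 or CMA 4 (adjusted p up to 0.72).

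Muscle, interferon, vascular and mitochondrial genes were lower under CMA. All 23 skeletal muscle genes were lower, by a median of -0.73 (adjusted p = 3.24e-08, and adjusted p = 0.60 with an estimated correlation). Casq1 (ENSMUSG00000007122, chromosome 1, 172209894 to 172219868), the calcium store protein of muscle fibres, stood at 55.1 ± 22 against 115 ± 90.7 CPM (log2 fold change -1.05), and its log2 fold change was -0.54 without Ctrl 4. Of the interferon response list 27 of 29 members were lower, by a median of -0.21 (adjusted p = 0.00581, and adjusted p = 0.90 with an estimated correlation), and the call ended without Ctrl 4 or CMA 1 (adjusted p up to 0.546). The mitochondrially encoded list had a median of -0.17 (adjusted p = 0.00416, and adjusted p = 0.60 with an estimated correlation), not called without Ctrl 2 (adjusted p = 0.0545). Of 21 endothelial genes 18 were lower, by a median of -0.21 (adjusted p = 0.0345, and adjusted p = 0.90 with an estimated correlation), a call that ended without Ctrl 1, Ctrl 4, Ctrl 5, Ctrl 6, CMA 2, CMA 4 or CMA 5 (adjusted p up to 0.521).

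edgeR called 0 genes between CMA and Ctrl, with 1254 at an unadjusted p under 0.05, and DESeq2 and limma with sample quality weights each called 0. The interval lay within 2-fold for 85.9% of the 18573 genes. Camera called 11 lists, 7 higher and 4 lower, and 13 without Ctrl 3, Ctrl 4 and CM1 3 together. The lowest adjusted p of an exact permutation test of list scores was 0.594.

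CMC wounds were compared with control wounds to see the effect of medium from M2c macrophages. A matricellular factor and a growth factor of fibroblasts were higher. Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683), connective tissue growth factor, stood at 58.2 ± 17.6 CPM (SD, n = 5) against 25.2 ± 10.0 in Ctrl (n = 6), a log2 fold change of 1.2 (SE 0.27, 95% interval 0.64 to 1.76, adjusted p = 0.40). Pdgfc (ENSMUSG00000028019, chromosome 3, 81036416 to 81214040), a ligand of the platelet-derived growth factor receptors, stood at 42.0 ± 5.25 against 27.9 ± 5.8 CPM, a log2 fold change of 0.59 (SE 0.14, adjusted p = 0.40). Both lay above the control median in 5 of 5 libraries and were the 2 members of the growth factor list that passed when adjusted over the list alone, against 0 over all genes (list median 0.18, camera adjusted p = 0.00612, and adjusted p = 0.71 with an estimated correlation). The fibrillar collagen and matrix list had 25 of 27 members higher, by a median of 0.19 (adjusted p = 1.73e-04), and the matrix protease list 18 of 23, by 0.22 (adjusted p = 2.6e-04), both with an adjusted p = 0.71 with an estimated correlation. Fn1 (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200), fibronectin, stood at 3580 ± 1010 against 2230 ± 787 CPM (log2 fold change 0.68, SE 0.28). These 3 lists stayed called without any 1 library.

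Genes of macrophages and their M2-type activation were higher under CMC. Of the alternative activation list 17 of 23 members were higher, by a median of 0.40 (adjusted p = 2.6e-04, and adjusted p = 0.71 with an estimated correlation), a call that held without any 1 library. Cd209a (ENSMUSG00000031494, chromosome 8, 3743397 to 3748984), a C-type lectin of dendritic cells and macrophages with close paralogs, stood at 4.4 ± 0.496 against 2.07 ± 0.672 CPM (log2 fold change 1.07, SE 0.24) and passed when adjusted over either list that holds it. The macrophage list had a median of 0.12 (adjusted p = 0.014), lost without Ctrl 1, Ctrl 3, CMC 1, CMC 2 or CMC 3 (up to 0.239). C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), a complement subunit made by tissue macrophages, stood at 206 ± 48.6 against 158 ± 27.7 CPM, a log2 fold change of 0.39, or 0.23 without CMC 2. The monocyte and dendritic cell list had a median of 0.09 (adjusted p = 0.00424), lost without Ctrl 3 or CMC 3 (up to 0.239), the chemokine list 0.25 (adjusted p = 0.0101), lost without Ctrl 4, CMC 1 or CMC 3 (up to 0.137), and the neutrophil list 0.08 (adjusted p = 0.024), lost without Ctrl 2, Ctrl 4, Ctrl 5, CMC 1 or CMC 3 (up to 0.217). With an estimated correlation these 4 lists each had an adjusted p = 0.71.

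Cell cycle genes were lower under CMC, and red cell and fat genes higher. All 27 cell cycle genes were lower, by a median of -0.30 (adjusted p = 2.23e-08, and adjusted p = 0.71 with an estimated correlation). Mcm3 (ENSMUSG00000041859, chromosome 1, 20802968 to 20820312), a part of the replicative helicase, stood at 31 ± 3.95 against 40.3 ± 5.99 CPM; Ctrl 3 had the highest cell cycle score of all libraries. Of the erythrocyte list 5 of 6 members were higher, by a median of 0.74 (adjusted p = 0.00222), and of the adipocyte list 16 of 17, by 0.35 (adjusted p = 0.00107), both with an adjusted p = 0.71 with an estimated correlation. Both lists were checks of what the tissue taken held, and spanned 3.68-fold and 4.67-fold between libraries. Whether the tissue taken or the medium accounts for their shifts was not tested. Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465), an alpha globin with a near-identical copy, stood at 53.0 ± 19.4 against 29.2 ± 17.6 CPM, and Pck1 (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273), the glyceroneogenic enzyme of fat, at 24.8 ± 11.3 against 11.9 ± 6.77. These 3 calls and that of the ribosomal protein list (27 of 28 higher, median 0.09, adjusted p = 2.6e-04, and adjusted p = 0.71 with an estimated correlation) held without any 1 library. The mean shift of the cell cycle list, -0.26, was -0.16 without Ctrl 3, and that of the ribosomal protein list, 0.10, was 0.06 without CMC 1.

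The remaining called lists of CMC depended on single libraries, each with an adjusted p = 0.71 with an estimated correlation. The wound keratinocyte list had 19 of 21 members higher, by a median of 0.71 (adjusted p = 4.23e-04, and 0.0576 without CMC 1), and the hypoxia and glycolysis list 20 of 22, by 0.13 (adjusted p = 0.00222, and 0.0611 without CMC 1). The interferon response list had 26 of 29 lower, by -0.30 (adjusted p = 0.00221, and 0.286 without Ctrl 4). All 16 hair follicle genes were lower, by a median of -4.40, and 15 passed when adjusted over the list alone, 0 over all genes (adjusted p = 0.00105, and 0.301 without Ctrl 3). Krt83 had a log2 fold change of -7.48 (SE 1.97), and -2.68 without Ctrl 3. Without Ctrl 3, Ctrl 4 and CM1 3 together it was 0.17, and the mean shift of the hair follicle list was 0.64. Of 9 melanocyte genes 8 were lower, by a median of -2.64, and 8 passed over the list alone, 0 over all genes (adjusted p = 0.0114, and up to 0.239 without Ctrl 3 or CMC 3). The skeletal muscle list had a median of -0.40 (adjusted p = 0.00388), lost without Ctrl 2, Ctrl 4, CMC 1 or CMC 3 (up to 0.265).

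edgeR called 0 genes between CMC and Ctrl, with 1622 at an unadjusted p under 0.05, and limma with sample quality weights 0. DESeq2 called 4 with its default filtering, all higher in CMC, each with an adjusted p = 0.40 in edgeR. They were Cebpd (ENSMUSG00000071637, chromosome 16, 15887286 to 15891031), a transcription factor of acute inflammation (log2 fold change 1.23, SE 0.25, adjusted p = 0.014), Ccn2 (1.21, SE 0.26, adjusted p = 0.031), Wee1 (ENSMUSG00000031016, chromosome 7, 110122046 to 110143286), a kinase that delays mitosis (0.67, SE 0.15, adjusted p = 0.031), and Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), an RNA helicase on the Y chromosome (0.31, SE 0.07, adjusted p = 0.044). With the filtering tuned to 0.05, chosen after the default count had been seen, it called 1, Cebpd. The interval lay within 2-fold for 86.1% of the 18573 genes. Camera called 18 lists, 13 higher and 5 lower, and 6 without Ctrl 3, Ctrl 4 and CM1 3 together.

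A panel of 24 genes of macrophage state, inflammation, matrix, vessels and epidermis had been fixed for every comparison with Ctrl. In CM0 15 were higher and 9 lower, in CM1 20 and 4, in CMA 14 and 10, and in CMC 18 and 6. 1, 3, 2 and 0 of them, in the same order, had an unadjusted p under 0.05, and 0 passed when adjusted over the panel alone or over all genes. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), the arginase of M2-type macrophages, stood at 172 ± 259 CPM in Ctrl, 138 ± 64.5 in CM0, 208 ± 92.6 in CM1, 199 ± 154 in CMA and 230 ± 160 in CMC. Its log2 fold change was -0.32 in CM0, 0.27 in CM1, 0.21 in CMA and 0.42 in CMC, and without Ctrl 1 it was 1.03, 1.62, 1.56 and 1.77. Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase of M1-type macrophages, stood at 37.9 ± 63.2 CPM in Ctrl, 11.4 ± 13.2 in CM0, 14.3 ± 8.36 in CM1, 34.9 ± 68.1 in CMA and 69.6 ± 71.5 in CMC. Its log2 fold change was -1.73 in CM0, -1.43 in CM1, -0.14 in CMA and 0.86 in CMC, and without Ctrl 1 it was -0.27, 0.02, 1.32 and 2.33; without CMA 4 it was -3.12 in CMA. Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057), the macrophage mannose receptor, stood at 361 ± 98.4 CPM in Ctrl and between 328 ± 59.7 in CMA and 415 ± 83.4 in CMC; in CM0 its log2 fold change was -0.06, and -0.29 without CM0 3. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) lay between 26400 ± 2860 CPM in Ctrl and 29400 ± 4850 in CMA, with 95% intervals of the log2 fold change inside -0.30 to 0.47 in the 4 media; in CM1 it was 0.11, and -0.10 without CM1 4. Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369), the main growth factor of blood vessels, stood at 90.5 ± 63.9 CPM in Ctrl and 103 ± 19.5 in CMC, with a log2 fold change of 0.18 (SE 0.36). Without Ctrl 1 its log2 fold change was -0.07 in CM0 in place of -0.53, 0.32 in CM1 in place of -0.14, 0.47 in CMA in place of 0.01 and 0.65 in CMC, and it was -0.39 in CMA without CMA 4.

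**Figure D3:**
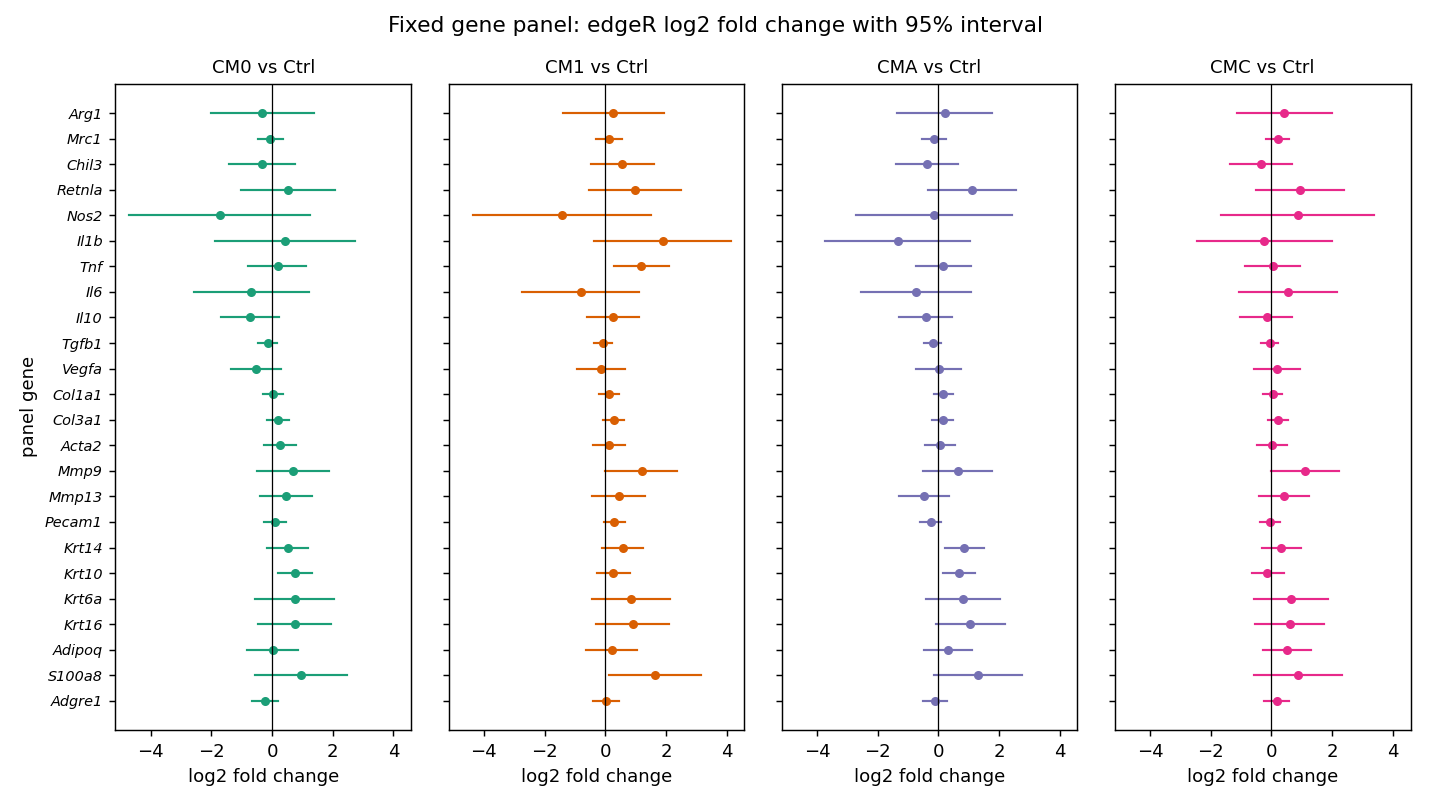
Log2 fold change of the 24 panel genes in each medium against Ctrl, with 95% intervals from edgeR. The intervals of Col1a1 and Col3a1 are narrow and include 0 in all 4 media, and that of Nos2 reaches from -4.72 to 1.25 in CM0.

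Taken as a mean over the 4 media, conditioned medium was compared with the control bandage to see what the media had in common. With the preset correlation, wound keratinocyte and ribosomal protein genes were called higher, and interferon response genes lower, in each of the 4 media. The media share their controls, and with an estimated correlation none of these lists was called in any medium. With the group labels of all libraries permuted, a count chosen after the result was seen, 23 of 100 labelings (the real one included) gave 3 or more lists called alike in 4 media, with a highest other of 11. Of the calls in single media, that of the wound keratinocyte list ended without CM0 4 in CM0 (adjusted p = 0.216) and without CMC 1 in CMC (0.0576), and that of the interferon list without Ctrl 4 in CMC (0.286) and without Ctrl 4 or CMA 1 in CMA (up to 0.546). In the mean of the media 20 of 21 wound keratinocyte genes were higher, by a median of 0.79, with scores of 4.53 ± 0.75 (SD, n = 18) against 3.67 ± 0.76 (n = 6; camera adjusted p = 5.67e-09, and adjusted p = 0.52 with an estimated correlation). Stfa3 (ENSMUSG00000054905, chromosome 16, 36450537 to 36455392), a protease inhibitor of a family with near-identical copies, stood at 138 ± 83.9 against 61.0 ± 30.4 CPM. All 28 ribosomal protein genes were higher, by a median of 0.15 (adjusted p = 1.62e-13), and 28 of 29 interferon response genes lower, by -0.29 (adjusted p = 1e-06), both with an adjusted p = 0.52 with an estimated correlation. Rps14 (ENSMUSG00000024608, chromosome 18, 60747098 to 60778546), a protein of the small ribosomal subunit, stood at 465 ± 50.4 against 403 ± 53.8 CPM and lay above the control median in 18 of 18 libraries. Igtp (ENSMUSG00000078853, chromosome 11, 58199556 to 58207591), an interferon-induced GTPase, had a log2 fold change of -0.46 (SE 0.17) and lay above it in 2 of 18. These calls held without any 1 of the 24 libraries, as did those of the matrix list (median 0.20, adjusted p = 1.37e-05), the neutrophil list (0.22, adjusted p = 0.00204), the chemokine list (0.28, adjusted p = 0.00204) and the skeletal muscle list (-0.51, adjusted p = 1.37e-05), each with an adjusted p = 0.52 with an estimated correlation. Single controls changed the size of these shifts. The mean shift of the interferon list, -0.28, was -0.13 without Ctrl 4, where the interferon score was 4.06 against 3.01 to 3.19 in the other controls. That of the matrix list, 0.18, was 0.11 without Ctrl 3, and that of the skeletal muscle list, -0.44, was -0.29 without Ctrl 2 and -0.25 without Ctrl 4. That of the neutrophil list, 0.50, was 0.81 without Ctrl 1 and 0.31 without Ctrl 4, and that of the chemokine list, 0.57, was 0.92 and 0.33.

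Other calls of that mean leaned on single libraries, above all Ctrl 3. All 27 cell cycle genes were lower, by a median of -0.23 (adjusted p = 1.34e-06, and adjusted p = 0.52 with an estimated correlation), and the adjusted p was 0.055 without Ctrl 3. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), the proliferation marker Ki-67, had a log2 fold change of -0.33 (SE 0.15), and -0.13 without Ctrl 3. Without Ctrl 3, Ctrl 4 and CM1 3 together the mean shift of the cell cycle list was 0.01 and the log2 fold change of Mki67 0.005. All 16 hair follicle genes were lower, by a median of -3.24 (adjusted p = 0.042, and adjusted p = 0.75 with an estimated correlation), and all 9 melanocyte genes, by -1.85 (adjusted p = 0.0376, and adjusted p = 0.63 with an estimated correlation). Of these, 15 and 8 passed when adjusted over the list alone, 0 over all genes. The hair follicle call ended without Ctrl 3, Ctrl 4, CMA 1, CMA 4, CMA 5, CMC 2, CMC 3 or CMC 4 (adjusted p up to 0.63), and the melanocyte call without Ctrl 3, Ctrl 4, CM0 3, CM0 4, CM1 3, CMA 1, CMA 4 or CMC 3 (up to 0.977). The matrix protease call (median 0.13, adjusted p = 0.003) ended without Ctrl 3 (adjusted p = 0.123), as did those of the alternative activation list (0.14, adjusted p = 0.0145, and 0.237 without it) and of the monocyte and dendritic cell list (0.05, adjusted p = 0.0123, and 0.691 without it). The cornified keratinocyte call (0.30, adjusted p = 6.43e-05) ended without Ctrl 6 (adjusted p = 0.107). Each of these 4 lists had an adjusted p = 0.52 with an estimated correlation. Without Ctrl 3 the mean shift of the hair follicle list was 0.50 in place of -0.57, that of the melanocyte list 0.03 in place of -0.54, and that of the endothelial list -0.02 in place of 0.09. The number of called lists, 21 with 15 higher and 6 lower, was 10 without Ctrl 3 and 6 without Ctrl 3, Ctrl 4 and CM1 3 together. edgeR called 0 genes for the mean of the media, with 1788 at an unadjusted p under 0.05, limma with sample quality weights 0, and DESeq2 1, Vgll3 (log2 fold change 0.29, SE 0.06, adjusted p = 0.039), or 0 with its filtering tuned to 0.05. Without Ctrl 2 edgeR called 5, each with an adjusted p = 0.047. They were the hair keratins Krt81, Krt83 and Krt87 (log2 fold change -5.92, -6.22 and -5.44), the replication factor Wdhd1 (-0.47) and Ddx3y (0.28).

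The 4 comparisons with Ctrl resembled one another across genes, and sharing a set of controls can produce a resemblance of that size. Over 18978 genes, which are not independent replicates, Pearson's r between the log2 fold changes of a pair of media averaged 0.57, from 0.49 for CMA with CMC to 0.66 for CM1 with CMC. Unchanged groups were simulated by redrawing all libraries, controls included, from the deviations of libraries from their group means. The comparisons of a simulation shared its redrawn controls, so the real 6 control libraries were not held fixed. The simulated mean r was 0.40 (SD 0.14), and 12 of 100 simulations reached the observed mean. The mean covariance was 0.0387 against 0.0246 simulated, reached in 7 of 100. With the controls split so that the comparisons of a pair used different control libraries, the mean r was 0.09.

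Between media, CMA and CMC differed in the largest number of lists, and the genes of upper epidermis and macrophages stood on opposite sides. Krt10 was at 2170 ± 863 CPM in CMA and 1240 ± 334 in CMC (SD, n = 5 each), a log2 fold change of 0.80 (SE 0.27, 95% interval 0.25 to 1.36, adjusted p = 0.79). Of the cornified keratinocyte list 22 of 23 members were higher in CMA, by a median of 0.53, with scores of 7.85 ± 0.29 against 7.28 ± 0.47 (exact permutation p = 0.0476; camera adjusted p = 3.18e-09, and adjusted p = 0.68 with an estimated correlation). Of the macrophage list 18 of 20 were lower in CMA, by a median of -0.29 (adjusted p = 1.9e-05, and adjusted p = 0.68 with an estimated correlation), with C1qc (ENSMUSG00000036896, chromosome 4, 136889804 to 136893065), a complement subunit of tissue macrophages, at 164 ± 29.3 against 223 ± 48.4 CPM. Cell cycle genes were higher in CMA in 26 of 27 cases (median 0.22, adjusted p = 5.07e-05), hair follicle genes in 16 of 16 (median 2.42, adjusted p = 8.17e-05), and matrix protease genes lower in 22 of 23 (median -0.23, adjusted p = 4.29e-04), each with an adjusted p = 0.68 with an estimated correlation. These 5 calls held without any 1 library. The mean shift of the macrophage list, -0.28, was -0.15 without CMA 2, that of the hair follicle list, 1.63, was 1.01 without CMA 3, and that of the cell cycle list, 0.19, was 0.12 without CMA 3. edgeR called 0 genes, with 1169 at an unadjusted p under 0.05, and DESeq2 and limma with sample quality weights 0 each. Camera called 17 lists, 7 higher and 10 lower in CMA. The lowest adjusted p of an exact permutation test of list scores was 0.492.

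Between CM1 and CMA the endothelial list had the smallest p. All 21 endothelial genes were higher in CM1, by a median of 0.43, with scores of 5.18 ± 0.21 (SD, n = 4) against 4.76 ± 0.16 (n = 5; exact permutation p = 0.0317; camera adjusted p = 8.63e-16, and adjusted p = 0.56 with an estimated correlation). 6 of them passed when adjusted over the list alone, 0 over all genes. Sox17 stood at 8.42 ± 0.957 against 5.4 ± 0.574 CPM (log2 fold change 0.64, SE 0.18, adjusted p = 1) and Egfl7 (ENSMUSG00000026921, chromosome 2, 26580014 to 26593120), a protein secreted by growing vessels, at 58.1 ± 12.3 against 39.0 ± 4.42. The chemokine list was higher in CM1 by a median of 0.95 (adjusted p = 2.77e-04, and 0.0502 without CM1 3), the neutrophil list by 0.67 (adjusted p = 3.69e-04), and all 23 cornified keratinocyte genes were lower, by -0.36 (adjusted p = 2.03e-05), each with an adjusted p = 0.66 with an estimated correlation. The mean shift of the cornified list, -0.41, was -0.24 without CM1 4. The neutrophil score was highest in CM1 3, at 4.87, against 2.88 to 3.81 in the other CM1 libraries. Ccl4 stood at 16.3 ± 26.3 against 1.46 ± 0.775 CPM, with a log2 fold change of 3.48, or 1.14 without CM1 3. edgeR called 0 genes, with 759 at an unadjusted p under 0.05, and DESeq2 and limma with sample quality weights 0 each. Camera called 12 lists, 8 higher and 4 lower in CM1. The lowest adjusted p of an exact permutation test of list scores was 0.685.

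CM1 was lower than CMC and CM0 in transcripts of the mitochondrial genome. All 11 of these genes were lower than in CMC, by a median of -0.26, with scores of 6.16 ± 0.08 (SD, n = 4) against 6.44 ± 0.14 (n = 5; exact permutation p = 0.0159; camera adjusted p = 1.54e-08, and adjusted p = 0.20 with an estimated correlation). All 11 were also lower than in CM0, by -0.23 (exact permutation p = 0.0286, the smallest that 70 divisions allow; camera adjusted p = 2.76e-05, and adjusted p = 0.43 with an estimated correlation). mt-Nd1 (ENSMUSG00000064341, chromosome M, 2751 to 3707), a subunit of respiratory complex I, stood at 598 ± 39.3 CPM in CM1, 711 ± 67.4 in CMC and 701 ± 81.0 in CM0. Skeletal muscle scores were lower in CM1 as well, at 7.28 ± 0.49 against 7.54 ± 0.74 in CMC and 7.79 ± 0.67 in CM0. Ctrl 4 scored highest of all libraries in muscle genes, at 8.87, and in mitochondrial genes, at 6.66. Within CM0 both scores were highest in CM0 2, at 8.73 and 6.6. CMA 3 scored lowest in muscle genes, at 6.47, with a mitochondrial score of 6.08. Within CM1 the lists parted, with the highest muscle score, 7.93 in CM1 3, beside a mitochondrial score of 6.08. Whether muscle in the tissue accounts for the mitochondrial difference was not tested. Against CMC all 21 endothelial genes were higher in CM1 (median 0.24, adjusted p = 6.14e-07, and adjusted p = 0.99 with an estimated correlation) and all 6 erythrocyte genes lower (median -0.77, adjusted p = 2.63e-04, and adjusted p = 0.60 with an estimated correlation). Against CM0 all 20 macrophage genes were higher (median 0.22, adjusted p = 1.13e-04, and adjusted p = 0.61 with an estimated correlation), as were 20 of 22 monocyte and dendritic cell genes (median 0.33, adjusted p = 2.78e-05, and adjusted p = 0.43 with an estimated correlation). Aif1 (ENSMUSG00000024397, chromosome 17, 35170991 to 35176068), a macrophage actin-bundling protein, had a log2 fold change of 0.48 (SE 0.18) against CM0. These 6 calls held without any 1 library. Against CMC the mean shift of the endothelial list, 0.24, was 0.15 without CM1 4. Against CM0 that of the mitochondrially encoded list, -0.21, was -0.13 without CM0 2, that of the macrophage list, 0.23, was 0.14 without CM1 2, and that of the monocyte and dendritic cell list, 0.30, was 0.19 without CM1 2. edgeR called 0 genes in either comparison, with 514 (CMC) and 422 (CM0) at an unadjusted p under 0.05, and DESeq2 and limma with sample quality weights 0 each. Camera called 8 lists against CMC, 13 without CM1 2 and 4 without CMC 5, and 13 against CM0, 4 without CM0 2. The lowest adjusted p of an exact permutation test of list scores was 0.492 against CMC and 0.709 against CM0.

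CMA and CMC were each compared with CM0 to see what polarisation to an M2 state adds. Endothelial genes were lower in CMA than in CM0 in 20 of 21 cases, by a median of -0.29 (adjusted p = 2.32e-07, and adjusted p = 0.77 with an estimated correlation). Tek stood at 32.4 ± 6.85 CPM (SD, n = 5) against 47.1 ± 10.4 (n = 4), a log2 fold change of -0.54 (SE 0.17, adjusted p = 1). Matrix genes were lower in 25 of 27 cases (median -0.16, adjusted p = 5.61e-04, and adjusted p = 0.77 with an estimated correlation). In CMC all 20 macrophage genes were higher than in CM0, by a median of 0.31 (adjusted p = 2e-06, and adjusted p = 0.78 with an estimated correlation). C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187), a complement subunit, stood at 270 ± 47.3 against 205 ± 34.5 CPM. Alternative activation genes were higher in 21 of 23 cases (median 0.41, adjusted p = 3.24e-05, and adjusted p = 0.78 with an estimated correlation), and cornified keratinocyte genes lower in 22 of 23 (median -0.30, adjusted p = 3.24e-05, and adjusted p = 0.81 with an estimated correlation), with Krt10 at 1240 ± 334 against 2310 ± 594 CPM. These 5 calls held without any 1 library. In CMA the mean shift of the endothelial list, -0.26, was -0.17 without CM0 4 and that of the matrix list, -0.20, was -0.12 without CMA 5; in CMC that of the cornified list, -0.38, was -0.21 without CMC 2. edgeR called 0 genes in either comparison, with 596 (CMA) and 706 (CMC) at an unadjusted p under 0.05, and DESeq2 and limma with sample quality weights 0 each. Camera called 13 lists for CMA, 6 without CM0 2 and 6 without CMA 3, and 9 for CMC.

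Cell types with no called list against Ctrl in any medium were those of the sebaceous gland, contractile myofibroblasts, T and NK cells, B and plasma cells, mast cells, lymphatic endothelium and Schwann cells, together with the classical activation genes of M1-type macrophages. The medians of these 8 lists lay between -0.17 and 0.18 and their lowest camera adjusted p was 0.134. When adjusted over the list alone, 1 classical activation gene and 1 B and plasma cell gene passed in CM0 and 2 B and plasma cell genes in CM1, against 0 over all genes. Classical activation genes scored 2.34 ± 0.70 in Ctrl (SD, n = 6), 2.32 ± 0.55 in CM0, 2.65 ± 0.62 in CM1, 2.16 ± 0.49 in CMA and 2.65 ± 0.57 in CMC. Myofibroblast genes scored 5.61 ± 0.08 in Ctrl and between 5.50 ± 0.11 in CM1 and 5.65 ± 0.17 in CM0. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), the smooth muscle actin of myofibroblasts, stood at 168 ± 50 CPM in Ctrl and between 170 ± 24.2 in CMC and 201 ± 59.8 in CM0.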

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

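The 2 tests on hair follicles in this part were chosen only after the result was seen; the search for libraries far from the rest of their group was not. Of 285 groups of libraries searched, 16 held a library whose gap to the nearest other was large for the spread of its group. Chance gives about 1 in 20, or 14 of 285, so single entries below need no cause beyond chance. All values are log2 CPM, of a gene or as the mean of a list.

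In Ctrl, the hypoxia and glycolysis score was 7.37 in Ctrl 1 (others 6.16 to 6.46) and the immediate early score 5.54 in the same library (others 4.78 to 5.04). The interferon response score was 4.06 in Ctrl 4 (others 3.01 to 3.19), the lymphatic endothelial score 3.54 in Ctrl 3 (others 3.76 to 3.84) and Mrc1 9.11 in Ctrl 6 (others 8.22 to 8.55). In CM0 the monocyte and dendritic cell score was 3.3 in CM0 2 (others 3.67 to 3.73). In CM1 the fibrillar collagen and matrix score was 10.89 in CM1 4 (others 10.31 to 10.39), the matrix protease score 6.59 in CM1 4 (others 6.28 to 6.32) and the alternative activation score 5.38 in CM1 2 (others 4.69 to 4.77).

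In CMA, 1 wound was low in wound keratinocyte genes, Krt14 and S100a8. In CMA 5 the wound keratinocyte score was 3.45 (others 4.83 to 5.34), Krt14 10.97 (others 11.86 to 12.15) and S100a8 4 (others 6.62 to 7.61). The Schwann cell score was high in the same library, at 3.45 (others 2.72 to 2.87). The classical activation score was 3.02 in CMA 4 (others 1.83 to 2.03). In CMC, Il1b was 0.1 in CMC 5 (others 3.79 to 4.84) and Col1a1 14.49 in CMC 2 (others 14.75 to 14.82).

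Hair follicle genes were lower in the media than in Ctrl by -0.56 in mean score. Without Ctrl 3 the media lay above the 5 other controls by 0.51, with those controls at 1.12 ± 2.18 (SD), so the sign of the difference came from Ctrl 3. If wounds differed in how much hair-bearing skin was taken, pigment genes of the hair bulb would follow the hair keratins. After removal of group means the hair follicle and melanocyte scores had a Pearson's r of 0.96 and a Spearman's rho of 0.94 over 24 libraries (permutation p = 1e-05 for each, the smallest that 100000 permutations give), and r was 0.93 without Ctrl 3 and CMA 3. Uneven hair-bearing skin in the tissue taken may account for the hair and pigment calls. A difference in hair growth between wounds would raise both scores together too, so the correlation cannot tell these apart. The sebaceous gland score spanned 1.81-fold between libraries, against 289-fold for the hair follicle score, and was 3.93 in Ctrl 3 and 3.39 in CMA 3. A difference in hair growth, or an effect of the media on it, stays open as untested.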

How the results depend on the processing

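The omission of Ctrl 3, Ctrl 4 and CM1 3 together and DESeq2 with filtering tuned to 0.05 were chosen only after the data were seen, and the other alternatives were set before. No paired analysis was possible because the labels give no replicate numbers. At these group sizes the 95% intervals lay within 2-fold for 83% to 86.1% of the 18573 genes at 1 CPM or more in comparisons between pairs of groups, and for 93.3% in the mean of the media. Size factors of DESeq2 moved log2 fold changes by at most 0.004 for all genes together. A log2 fold change counted as the same when it moved by less than its SE in the main fit, which is a wide margin for genes such as Krt83. Over 269 values of named genes and 4673 alternatives, 4539 were the same in that sense and 133 moved. Only 1 passed a threshold it had missed, Ccn2 in CMC with DESeq2 (log2 fold change 1.209). Counted apart from these classes, 103 differed in sign. Over 148 list calls and 2403 alternatives, 1759 held, 628 were lost and 16 were reversed; the cause was not tested.

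The number of called lists was 0 in all 11 comparisons with an estimated correlation and 0 with fry. Against 0 genes in edgeR, DESeq2 called 1 for CM0, 1 for CM1, 4 for CMC, 1 for the mean of the media and 1 for any difference, and with filtering tuned to 0.05 it called 1 for CM0, 1 for CM1, 1 for CMC and 1 for any difference. Without Ctrl 3, Ctrl 4 and CM1 3 together the called lists were 7 for CM0, 6 for CMC and 6 for the mean. The mean r between the comparisons with Ctrl, 0.57, was 0.091 with split controls and 0.503 to 0.663 without 1 library.

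Without 1 library at a time the called lists ranged from 4 to 15 for CM0 against Ctrl, 13 to 19 for CM1, 8 to 13 for CMA, 12 to 20 for CMC and 10 to 21 for the mean. Between media the ranges were 4 to 17 for CM1 and CM0, 6 to 12 for CMA and CM0, 7 to 13 for CMC and CM0, 11 to 17 for CM1 and CMA, 4 to 13 for CM1 and CMC, and 12 to 20 for CMA and CMC. Genes called by edgeR ranged from 0 to 1 for CM0 and 0 to 5 for the mean, and were 0 in each other comparison, and list scores past the exact permutation test were 0 in each of the 4 comparisons with Ctrl.

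Reversed mean shifts without Ctrl 3, Ctrl 4 and CM1 3 together were 0.038 for cell cycle in CM0, 1.415 for hair follicle, 0.018 for cell cycle and 0.235 for melanocyte in CM1, and 0.64 for hair follicle in CMC. In the mean of the media they were 1.468 for hair follicle, -0.018 for endothelial, 0.01 for cell cycle, -0.021 for hypoxia and glycolysis and 0.397 for melanocyte. With the preset correlation camera then called the hair follicle list in the opposite direction, higher in CM1 (camera adjusted p = 4.04e-04) and in the mean (1.52e-07). Without 1 library the shift ranged from -1.375 to 0.259 for hair follicle in CM1 (highest without Ctrl 3), from -0.059 to 0.331 for interferon response in CMC against CM0 (lowest without CM0 4) and from -0.589 to 0.157 for adipocyte in CM1 against CMC (highest without CM1 4). In the mean it ranged from -1.137 to 0.498 for hair follicle, from -0.018 to 0.168 for endothelial and from -0.806 to 0.03 for melanocyte, each turned by Ctrl 3; the cause was not tested.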

Other observations

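The tests on clock, glucocorticoid-induced and ribosomal protein genes and the comparison with other divisions of the libraries were chosen only after the result was seen. Some genes of the circadian clock and some induced by glucocorticoids stood higher in CMC than in Ctrl; those named here were chosen after their values were seen, and the scores of both groups missed an exact permutation p of 0.05. Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960), a repressor of the clock, was at 133 ± 22.8 CPM (SD, n = 5) against 84.4 ± 17.8 in Ctrl (n = 6), a log2 fold change of 0.65 (SE 0.2, adjusted p = 0.55). Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324) was at 41.7 ± 8.22 against 26.4 ± 6.85 CPM, Per3 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665) at 123 ± 14.1 against 95.9 ± 17 and Ciart (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251) at 6.69 ± 0.914 against 4.84 ± 1.29. Wee1, a kinase under clock control, was at 36.1 ± 5.21 against 22.6 ± 3.06 CPM, a log2 fold change of 0.67 (SE 0.14, adjusted p = 0.40). Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), the activator BMAL1 that is expressed in the opposite phase, was at 18.9 ± 4.12 against 24.3 ± 2.08 CPM. Of the genes induced by glucocorticoids, Tsc22d3 (ENSMUSG00000031431, chromosome X, 140539528 to 140600659) was at 124 ± 33.5 against 69.7 ± 15.8 CPM and Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) at 97.5 ± 12.3 against 70.6 ± 15.5. Cebpd, induced by glucocorticoids and by inflammation, was at 40.4 ± 16.2 against 17.3 ± 4.91 CPM. Among the other day-phase genes and genes induced by glucocorticoids, the log2 fold change was -0.26 for Nr1d1, -0.14 for Bhlhe41, -0.12 for Pdk4 and -0.06 for Mt2, and from 0.1 for Mt1 to 0.82 for Errfi1 in the rest. The Per genes, Ciart, Wee1, Tsc22d3, Fkbp5 and Cebpd lay above the control median in 5 of 5 CMC libraries. Per1 was also at 119 ± 29.3 CPM in CMA, and at 86.1 ± 18.8 in CM0 and 78.4 ± 26.9 in CM1.

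For the clock genes in CMC, the hour of tissue collection is a candidate explanation, and it is not given in the sources used here. An index of 10 day-phase minus 4 night-phase clock genes was 1.27 ± 0.38 in CMC and 0.94 ± 0.32 in Ctrl, a difference of 0.33 (exact permutation p = 0.145), with 0.28 for the day-phase genes alone (exact permutation p = 0.0649) and -0.05 for the night-phase genes alone (exact permutation p = 0.706). The score of 10 genes induced by glucocorticoids differed by 0.33 as well (6.42 ± 0.26 against 6.09 ± 0.24, exact permutation p = 0.0541), and with library depth as a covariate the clock index differed by 0.3 (SE 0.2). None of these values decides between time of day, stress hormone exposure, depth and an effect of the medium, because the hour may differ between groups and glucocorticoids also induce Per1.

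Cytosolic ribosomal protein genes were called higher by camera with its preset correlation in each of the 4 media, which share their controls, but in 0 with an estimated correlation (adjusted p = 0.46 to adjusted p = 0.91). Their score was higher by 0.15 (SE 0.07) in the media than in Ctrl (exact permutation p = 0.0279 over 134596 divisions of the libraries, unadjusted, 1 of 31 lists). These transcripts are short, so a trend of counts on transcript length and GC content could raise them together. After each library's trend on length and GC was removed the difference was 0.15 (SE 0.06, exact permutation p = 0.0162) and the list was still called in 4 media with the preset correlation. That the difference kept its size argues against that trend as the whole cause. With the neutrophil score as a covariate the difference was 0.11 (SE 0.06), so neutrophil content cannot be told apart from the medium as the origin of a part of it. A shared effect of the media, or of macrophage medium against the control bandage, stays open as untested. The numbers in the sample titles were unevenly spread, with 18 to 24 held by Ctrl 3 to Ctrl 6, CM0 4, CM1 4 and CMC 5. What these numbers stand for is not given in the sources used here, and whether the score follows them was not tested.

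The numbers of genes and lists called were compared with those from other divisions of the same libraries into groups of the same sizes. For genes, edgeR called 0 in each comparison, so each of the 22 divisions had to give as many and the comparison says nothing about chance. The highest other count was 19 for CM0 against Ctrl, 1 for CM1 against Ctrl, CMA against Ctrl and CM1 against CM0, and 0 in the rest. A division that mixes CM0 and Ctrl libraries and calls 19 genes may reflect a structure of the samples other than their groups or unusual libraries that fell together by chance among these 22 divisions, and this was not tested.

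For gene lists, the real division gave more than any other drawn for CMA against CMC, with 17 lists and a highest other of 16 (1 of 100 as many, the real one included), and for the mean of the media against Ctrl, with 21 and 19 (1 of 100). Taken alone each share is under 0.05, but 1 of 100 is the smallest these divisions allow. Adjusted over the 11 comparisons it is 0.055, so chance is not excluded. Both counts depend on single libraries. The mean of the media gave 10 lists without Ctrl 3 and 6 without Ctrl 3, Ctrl 4 and CM1 3 together, and CMA against CMC gave 12 without CMA 3. Chance could not be excluded for CM0 against Ctrl, with 11 lists and a highest other of 21 (62 of 100), CM1 against Ctrl, with 15 and 23 (36 of 100), CMA against Ctrl, with 11 and 19 (70 of 100), or CMC against Ctrl, with 18 and 21 (11 of 100). The same holds between media for CM1 against CM0, with 13 and 18 (18 of 35), CMA against CM0, with 13 and 17 (19 of 100), CMC against CM0, with 9 and 18 (59 of 100), CM1 against CMA, with 12 and 16 (37 of 100), and CM1 against CMC, with 8 and 18 (82 of 100). For CMA against CMC and for the mean of the media the divisions speak of the number of lists, not of any single list.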
